A study of Arabidopsis thaliana with 21 samples.

How the data were processed

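The series measured messenger RNA and small RNA in Arabidopsis thaliana plants with mutations in AtDXO1 (AT4G17620, here DXO1), an enzyme that per the series title removes NAD caps from RNA and acts as an exonuclease. The 21 libraries had 3 replicates per group. The 9 mRNA libraries came from wild-type Col-0 plants and from the mutants labelled dxo1-1 and dxo1-2, at 16 days. The 12 small RNA libraries came from Col-0, dxo1-2, dcl4-2 and the cross dxo1-2dcl4-2, at 10 days. DCL4 is a Dicer-like enzyme that cuts double-stranded RNA into 21-nt small interfering RNAs. The labels call every sample rosette leaves, while the extract protocol for small RNA names seedlings. Growth was on plates and then in soil under long days, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

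The deposited mRNA values are FPKM, fragments per kilobase of transcript scaled by depth, per the labels. TopHat2 2.1.0, RSEM 2.1.30 and the build TAIR10 are named for these samples, per the submitters' processing notes. Their order and settings are not given in the sources used here. No counts came with the FPKM table. Low values of genes of 550 to 1300 bases lay near whole multiples of what 1 fragment is worth, and from these a depth of 17.5 to 20.8 M fragments per library was estimated. The same fit put the mean fragment length at 325 bases in Col-0 replicates 1 and 3, at 375 in Col-0 replicate 2, and at 375 to 385 in the mutant libraries. With 86.2 to 94.1% of the low values near whole multiples, these steps were used to describe depth and for no test.

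The deposited small RNA values are a signal, normalized reads per gene in separate tables for 21-nt, 22-nt and 24-nt RNAs, per the labels. Bowtie and TAIR10 are named for them, per the submitters' processing notes; how multiply mapping reads were treated, and whether strand was used, is not given in the sources used here. Each column held whole multiples of a single step. Of the values above 0, 100% in each of the 3 tables were whole within a tolerance of 0.001 reads. The steps matched size factors recomputed as a median of ratios over genes with reads in all 12 libraries (592, 989 and 1938 genes in the 21-nt, 22-nt and 24-nt tables) with a largest deviation of 0.0%. Whole reads were therefore recovered. They summed to 173804 to 1403794 reads per library over the 3 tables. That sum is the part of a library assigned to genes in 3 length classes, not its full depth, which is not given in the sources used here.

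The reference table of RefSeq, assembly TAIR10.1, differs in name from the authors' build, so none of its coordinates are printed. It gave symbols, biotypes and the order of neighbouring genes. Locus tags matched 32835 of 33602 genes of the FPKM table and 31722 of 32420 genes of the small RNA tables. By its biotypes, 178 microRNA genes and 4829 pseudogenes had a place in the small RNA tables. None (0) of the 8 trans-acting siRNA loci of the gene lists had one, so their small RNAs are not analysed here. The reference has no biotype for transposable element genes, so the loci called pseudogenes here may include such genes. Reads at genes with near-identical copies, and at overlapping or antisense genes, could not be assigned with certainty, and values of such genes are reported as uncertain.

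Comparisons, tests, gene lists and alternatives were written before the data were examined, except where stated. For mRNA, limma 3.58.1 (with a mean-variance trend) was run in R 4.3.3 on log2(FPKM + 1) of genes with a mean of at least 1 FPKM over the 9 libraries, in one fit over all 3 groups. The contrasts were each mutant against Col-0, the mean of both alleles against Col-0, and the alleles against each other. Fold changes on this scale understate the change of low genes. For small RNA, edgeR was planned for counts and limma for normalized values. The tables held normalized values, so limma on log2(normalized reads + 0.5) of features with a mean of at least 1 over the 12 libraries gave the main results, in one fit over all 4 groups and separately per size class. The contrasts were dxo1-2 against Col-0, dcl4-2 against Col-0, dxo1-2dcl4-2 against each single mutant, and the difference between the dxo1-2 effects in the dcl4-2 and the wild-type background. The quasi-likelihood test of edgeR 4.0.16 on the recovered reads was added after the data were seen, with library sizes and TMM factors over the 3 classes summed. It tested 1495, 2032 and 3465 features in the 21-nt, 22-nt and 24-nt classes. It called 59, 82, 288, 269 and 127 features in the 5 contrasts at 21-nt in the order given, 17, 119, 367, 217 and 162 at 22-nt, and 0, 25, 353, 414 and 60 at 24-nt. Throughout, a gene passed at a Benjamini-Hochberg adjusted p under 0.05, and unless stated otherwise an adjusted p is from limma.

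Folds of small RNA features are ratios of summed reads over summed size factors. Where a group had 0 reads, the fold is a lower bound against 3 reads over the whole group, written as at least. Other folds of this kind carry a 95% exact interval for the ratio of reads. These intervals and floors cover counting error only. Shares of size classes were compared by two-sided exact permutation tests, where 3 libraries against 3 cannot give a p below 0.1.

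The 25 gene lists held 422 genes, all of which had a place in the FPKM table and 414 in the small RNA tables. They covered salicylic acid immunity, NLR immune receptors, pattern-triggered immunity and camalexin, jasmonate and ethylene response, light-harvesting antenna, nuclear-encoded photosystems, Calvin-Benson cycle, chloroplast-encoded genes, chlorophyll synthesis, RNA decapping and decay, small RNA machinery, heat and oxidative stress, senescence, NAD metabolism, cell division, clock and flowering, guard cells, vasculature, shoot meristem and flower, root, seed storage, trans-acting siRNA loci, pentatricopeptide repeat (PPR) siRNA loci, auxin receptors, and nitrate reductase with SMXL genes. MicroRNA genes and pseudogenes of RefSeq were added for small RNA; a list of transposable element genes was planned and was not run, because the reference has no such biotype. Lists with at least 3 tested members were tested by camera with a preset correlation of 0.01, and again with an estimated correlation, and by fry for a balance to one side, which makes no comparison with other genes and so moves with a shift of all genes; p-values were adjusted over the lists of each contrast. Camera compares a list with the other genes, so a list can pass as lower when its median lies at or above 0.

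Named genes followed a rule fixed in advance. They were DXO1 and DCL4; in mRNA up to 4 members per list with the smallest adjusted p, and the 5 highest and 5 lowest changes in the mean of both alleles among genes with a mean of at least 5 FPKM whose mutant and Col-0 values did not overlap; in small RNA the 3 highest and 3 lowest changes per class and contrast with a mean of at least 5 normalized reads in a group and no overlap, and up to 3 members per list. Not every gene so named is discussed. Genes named outside the rule are marked as such.

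Alternatives changed the pseudocount (0.1), the filters, the scaling (median centring, quantile normalization, TMM factors within the class or none), the tool (edgeR, DESeq2 1.42.0), the fit (the 2 groups compared only, a fold of at least 2, a replicate block) and the libraries (each left out in turn). An mRNA fit on genes of at least 1000 bases and one with Col-0 replicate 2 as the only control were added after the fragment lengths were seen. Centring the libraries on their medians moved the median change of all tested mRNAs by -0.312 for the libraries labelled dxo1-1, -0.353 for dxo1-2 and -0.333 for their mean. In small RNA, centring moved it by up to 1.94 (21-nt, dxo1-2dcl4-2 against dxo1-2), and library size alone in place of TMM factors moved it by -1.23 to -1.24 for dxo1-2dcl4-2 against dcl4-2 and by -1.71 against dxo1-2.

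The fits were tested on simulated data with 200 changed genes, drawn from genes with a mean of at least 5 FPKM or 10 normalized reads. The simulated edgeR fits were scaled within the class, unlike the fits reported. For libraries labelled dxo1-1 against Col-0, limma recovered 89.6% of genes changed 1.5-fold, 94% at 2-fold and 100% at 4-fold among 18261 genes, with 5 calls among unchanged genes. In the real comparison 13902 of 18378 genes passed and all tested genes shifted by a median of 0.209. The simulation held no such shift, so it does not tell how many calls a shift of all genes would make. For small RNA (dxo1-2 against Col-0) the simulated folds were set to 2, 4 and 16 after a first run with smaller folds recovered few. At 21-nt (7515 features) limma recovered 3%, 17.9% and 56.1% at these folds, and edgeR (1319 features) 3.1%, 33.8% and 83.1%. At 22-nt limma (8222 features) recovered 1.5%, 11.9% and 66.7%, and edgeR (2181) 0%, 29.9% and 87.7%. At 24-nt limma (8280) recovered 1.5%, 29.9% and 87.9%, and edgeR (3362) 3%, 43.9% and 89.4%. Calls among unchanged features numbered 0 to 5. Small RNA features changed 4-fold or less were thus mostly missed in the simulation. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.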

Results

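DXO1 mRNA was lower in dxo1-2 and far higher in the libraries labelled dxo1-1 than in wild type. DXO1 (AT4G17620) stood at 10.04, 11.97 and 10.77 FPKM in Col-0, at 192.71, 195.46 and 248.56 in the libraries labelled dxo1-1, and at 6.67, 5.88 and 7.64 in dxo1-2. The mean was 10.93 ± 0.974 (SD, n = 3) in Col-0, 212.2 ± 31.5 in the libraries labelled dxo1-1 (log2 4.15, SE 0.11, adjusted p = 5.66e-11) and 6.73 ± 0.882 in dxo1-2 (log2 -0.63, SE 0.11, adjusted p = 0.000354). A gene-level FPKM does not tell which part of the transcript the fragments came from. DCL4, which makes 21-nt small interfering RNAs, stood at 3.19, 3.42 and 3.3 FPKM in Col-0, at 3.63, 3.54 and 4.11 in the libraries labelled dxo1-1, and at 4.37, 4.15 and 4.85 in dxo1-2. It passed the test in dxo1-2 (log2 0.34, adjusted p = 0.00536) and not in the libraries labelled dxo1-1 (log2 0.14, adjusted p = 0.169), and its mean change of 0.24 turned to -0.0903 when libraries were centred. No mRNA was measured in the dcl4-2 background. Small RNA reads at DXO1 and DCL4 numbered 0 to 31 per group and class and do not check the label of any line.

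**Figure D1:**
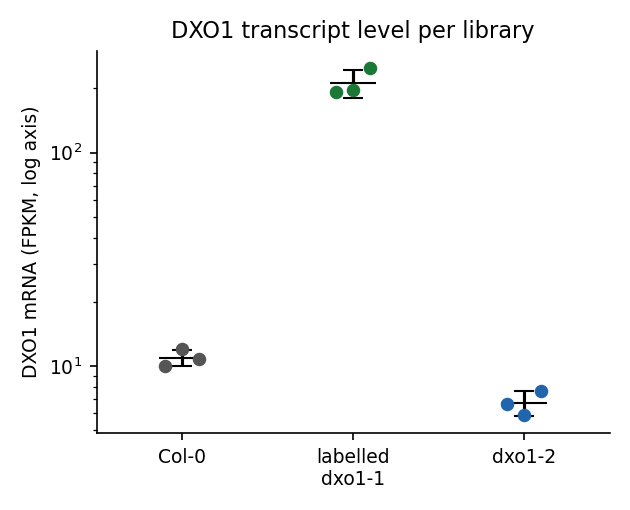
DXO1 mRNA in each of the 9 mRNA libraries (FPKM, log axis). Points are libraries, n = 3 per group; DXO1 is higher in the libraries labelled dxo1-1 than in Col-0.

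The highest changes shared by both mutants were at AT3G02480, LEA7 and immune genes. AT3G02480 rose from 7.747 ± 2.29 FPKM in Col-0 to 662.2 ± 32.7 in the libraries labelled dxo1-1 and 788.4 ± 50.3 in dxo1-2. LEA7, of the late embryogenesis abundant proteins, rose from 1.037 ± 0.342 to 102.5 ± 8.99 and 146.6 ± 5.83. The lowest were CSLA01 (16.17 ± 0.921 in Col-0, log2 -3.61 and -3.24), ASN1, an asparagine synthetase (85.83 ± 2.83 to 7.16 ± 0.635 and 6.833 ± 0.488), AT4G13575 (43.4 to 2.55 and 3.66), AT4G13860 (16.56 ± 4.68, listed at 0 in both mutants) and the defensin gene PDF1.2B (54.6 ± 28.7 to 6.737 ± 11.7 and 3.56 ± 6.17, adjusted p = 0.00839 and 0.00603). PDF1.2B has near-identical copies and is of uncertain level; PDF1.2A, named outside the rule like PDF1.2C, stood at log2 -0.37 and -0.55, and PDF1.2C at 0.17 and 0.16 without passing. In the mean of both alleles 9634 genes were higher and 4562 lower among 18378 tested (67.9% higher, limma). All tested genes shifted by a median of 0.23. After centring 6385 were higher and 8214 lower, and after quantile normalization 6488 and 7931, so which side held more genes depended on the scaling. With a fold of at least 2 the counts were 2981 higher and 717 lower.

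In the libraries labelled dxo1-1, where DXO1 was higher, 9116 genes were higher and 4786 lower than in Col-0 (65.6% higher). PR1, PR5 and PAD3 were among the most raised genes of the lists (log2 6.13, 5.85 and 5.72) and LHCB2.3 among the most reduced (log2 -2.35). Centred libraries gave 6325 higher and 8002 lower, and quantile normalization 6359 and 7831. A fold of at least 2 left 3134 and 955.

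In dxo1-2, 9520 genes were higher and 3890 lower than in Col-0 (71% higher). NIMIN1, PR1 and PR5 were among the most raised genes of the lists (log2 6.23, 5.61 and 5.38), and LHCB2.3 (log2 -1.95) and VSP2 (log2 -1.76) among the reduced ones. Centred libraries gave 5932 higher and 7807 lower, and quantile normalization 6131 and 7464. A fold of at least 2 left 2853 and 596.

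Immune genes of the salicylic acid pathway rose as a whole list. PR1, a marker of this pathway, rose from 59.71 ± 2.53 FPKM to 4247 ± 122 in the libraries labelled dxo1-1 and 2972 ± 146 in dxo1-2, and PR5 from 34.05 ± 2.09 to 2015 ± 22.6 and 1459 ± 28.1. NIMIN1, whose product binds the salicylic acid receptor NPR1, rose from 4.57 ± 0.209 to 321.8 ± 9.81 and 418.5 ± 17.0, and WRKY46 from 8.517 to 369.6 and 332. In the mean of both alleles 32 of 32 tested members were higher (median log2 3.35, camera adjusted p = 1.19e-14, and adjusted p = 0.0488 with an estimated correlation). This was the only mRNA list that passed in that comparison with an estimated correlation.

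Of 30 NLR immune receptor genes 27 were higher, 0 lower and 3 did not pass (median log2 0.79, camera adjusted p = 0.000317, adjusted p = 0.467 with an estimated correlation, 21 higher and 4 lower when centred). RPS2, a receptor for a bacterial effector, rose from 5.12 ± 0.255 FPKM to 20.16 ± 0.528 in the libraries labelled dxo1-1 and 28.86 ± 1.24 in dxo1-2. ADR1, a helper receptor, rose from 5.017 ± 0.599 to 35.7 ± 0.973 and 28.0 ± 0.909. Of 20 genes of pattern-triggered immunity and camalexin 17 were higher, 2 lower and 1 did not pass (median log2 1.08, camera adjusted p = 0.00159, adjusted p = 0.273 with an estimated correlation, 15 and 4 when centred). PAD3, which completes camalexin synthesis, rose from 8.947 ± 0.273 to 524.1 ± 11.1 and 85.81 ± 1.36, and SOBIR1, a co-receptor of receptor-like proteins, from 93.37 to 762.3 and 567.9. The jasmonate and ethylene list passed lower: 16 of 23 were lower, 5 higher and 2 did not pass (median log2 -0.60, -0.94 when centred, camera adjusted p = 8.68e-05, adjusted p = 0.151 with an estimated correlation). VSP2, a jasmonate-induced storage protein gene, fell from 644.6 ± 26.5 to 206.8 ± 6.76 and 189 ± 6.12, and AOS, of jasmonate synthesis, from 475.7 ± 14.9 to 150.8 ± 4.67 and 187.6 ± 4.98. The 5 higher members, named outside the rule, were ERF1 (log2 2.25 and 2.01), ERF2 (1.02 and 1.29), PR3 (2.04 and 1.18), PR4 (1.94 and 0.85) and JAZ1 (0.98 and 0.94).

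Most nuclear genes of photosynthesis were lower in both mutants. LHCB2.3, a light-harvesting protein gene with near-identical copies and so of uncertain level, fell from 2236 ± 61.0 FPKM to 437.3 ± 21.7 in the libraries labelled dxo1-1 and 576.2 ± 8.92 in dxo1-2. LHCB6 fell from 5383 ± 121 to 1806 ± 49.2 and 2033 ± 34.7. PSBP1, of the oxygen-evolving complex, fell from 5086 ± 27.3 to 2013 ± 37.7 and 2556 ± 55.1, and RBCS3B, a Rubisco small subunit gene with near-identical copies, from 14170 ± 454 to 6624 ± 249 and 6537 ± 59.1. CHLM, of chlorophyll synthesis, fell from 567.3 ± 25.9 to 210.5 ± 2.87 and 254.8 ± 3.54. In the mean of both alleles 17 of 17 antenna genes were lower (median log2 -1.13, camera adjusted p = 6.96e-15, adjusted p = 0.18 with an estimated correlation), as were 30 of 30 genes of photosystems (median log2 -0.87, 8.02e-19, adjusted p = 0.151 with an estimated correlation). Of 22 chlorophyll synthesis genes 20 were lower and 2 higher (median log2 -0.64, 1.27e-09, adjusted p = 0.18 with an estimated correlation), and in dxo1-2 alone 17 and 2; the regulator gene GLK1, named outside the rule, was higher in both mutants (log2 0.78 and 0.71). Of 19 Calvin-Benson genes 14 were lower, 4 higher and 1 did not pass (median log2 -0.29, 1.14e-05, adjusted p = 0.268 with an estimated correlation), and in dxo1-2 alone 12 were lower, 2 higher and 5 did not pass. Against the list the aldolase gene FBA1 rose from 743.2 ± 13.8 to 1665 ± 31.2 in the libraries labelled dxo1-1 and by log2 0.25 in dxo1-2, less than the shift that centring removed there. The size of these falls depended on the scaling. Medians of antenna, photosystem, chlorophyll synthesis and Calvin-Benson genes were -1.46, -1.21, -0.98 and -0.63 when centred (Calvin-Benson 18 lower and 1 higher), and -0.54, -0.59, -0.96 and -0.49 with quantile normalization (16 of 17 antenna and 27 of 30 photosystem genes lower). In dxo1-2 alone quantile normalization gave -0.42 for antenna genes, with 14 lower and 1 higher, and -0.50 for photosystem genes, with 25 lower and 1 higher. Of 17 chloroplast-encoded genes 3 were lower and 14 did not pass (2 lower adjusted over the list alone, camera adjusted p = 0.108), but the mutants differed. In the libraries labelled dxo1-1 5 were lower and 12 did not pass (median log2 -0.58, 0.0145, adjusted p = 0.546 with an estimated correlation). In dxo1-2 4 were higher, 2 lower and 11 did not pass (0 and 2 adjusted over the list alone, median log2 0.51, positive while camera put the list lower, 0.477), with PSBA at 2.07 and RBCL at 1.59, both named outside the rule. ATPB fell from 18.22 ± 2.52 to 7.773 ± 1.11 and 7.637 ± 1.38.

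Stress and senescence genes rose. All 20 tested heat and oxidative stress genes were higher in the mean of both alleles (median log2 2.04, camera adjusted p = 1.14e-05, adjusted p = 0.151 with an estimated correlation), 16 higher and 1 lower when centred. In dxo1-2 alone 17 were higher, 1 lower and 2 did not pass: FSD1, named outside the rule, was lower (log2 -0.26, adjusted p = 0.000245). OM66, a mitochondrial outer membrane protein gene, rose from 6.873 ± 0.594 FPKM to 85.93 ± 1.71 in the libraries labelled dxo1-1 and 79.49 ± 1.64 in dxo1-2. AOX1D, an alternative oxidase gene, rose from 2.75 ± 0.239 to 60.98 ± 1.42 and 22.15 ± 0.398. GSTF6 and GSTF7, near-identical glutathione transferase genes of uncertain assignment, rose from 135.3 and 110.8 to 1900.0 and 1645 in the libraries labelled dxo1-1 and 861.9 and 805.7 in dxo1-2. Of 14 senescence genes 12 were higher and 2 lower (median log2 1.31, 0.0119, adjusted p = 0.331 with an estimated correlation); SAG13 rose from 19.52 ± 1.3 to 689.7 ± 16.0 and 279.7 ± 8.14. Of 20 genes of NAD metabolism 12 were higher, 2 lower and 6 did not pass, and the list did not pass by camera (median log2 0.47, camera adjusted p = 0.3), while fry put it higher (2.3e-06). Centred libraries gave 10 higher and 6 lower (median 0.14) and quantile normalization 9 and 6 (0.12). NUDT7, a hydrolase gene active on NADH, rose from 39.19 to 179.5 and 209.0, and PARP2 from 2.237 to 11.41 and 8.983.

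Genes of RNA decay and small RNA production did not stand out from other genes as lists by camera, while fry, which makes no comparison with other genes, put both lists higher (adjusted p = 7.39e-05 each). Of 26 RNA decay genes 20 were higher, 2 lower and 4 did not pass (median log2 0.32, camera adjusted p = 0.329), but 7 were higher and 10 lower when centred. CAF1A, a deadenylase gene, rose from 28.43 ± 1.18 FPKM to 63.21 ± 3.31 in the libraries labelled dxo1-1 and 41.84 ± 2.32 in dxo1-2, and SOV, a 3'-to-5' exonuclease gene, fell from 16.18 ± 0.857 to 8.697 ± 0.303 and 8.867 ± 0.73. Of 25 genes of the small RNA machinery 13 were higher, 5 lower and 7 did not pass (median log2 0.20, 0.818), against 7 and 12 when centred. AGO2, an Argonaute gene of antiviral defence, rose from 5.1 ± 0.368 to 24.31 ± 0.388 and 19.39 ± 1.52, and RDR1, an RNA-dependent RNA polymerase gene, from 4.533 to 12.55 and 13.66.

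Among siRNA source loci the mRNAs moved both ways. NIA1, a nitrate reductase gene, rose from 48.66 ± 0.0656 FPKM to 102.3 ± 0.927 in the libraries labelled dxo1-1 and 88.48 ± 0.852 in dxo1-2, and its copy NIA2 from 419.6 ± 12.2 to 664.3 ± 11.3 and 700.4 ± 28.0. SMXL5 fell from 5.11 ± 0.405 to 2.943 ± 0.0351 and 2.943 ± 0.0404. The nitrate reductase and SMXL list had 2 higher and 1 lower of 3 (median log2 0.70, camera adjusted p = 0.693, fry higher, 1.32e-06). Among 4 auxin receptors TIR1 fell from 85.92 ± 4.78 to 55.5 ± 0.854 and 55.64 ± 2.8, while AFB2 rose from 24.57 to 33.62 and 33.68 (2 higher, 2 lower, median log2 0.00, mean -0.04, 0.561, 0 higher and 2 lower when centred). AFB3 rose by 0.37 and stood at -0.00948 after quantile normalization. TAS3A, a trans-acting siRNA precursor, fell from 43.81 ± 5.68 to 17.88 ± 3.23 and 23.31 ± 4.28, 1 of 5 trans-acting siRNA loci, with 4 not past the test (median log2 -0.22, 0.198, fry lower, 0.0145). Of 9 PPR loci 5 were higher, 2 lower and 2 did not pass (median log2 0.31, 0.985, fry higher, 0.00892, 2 and 3 when centred).

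FLC, a repressor of flowering, fell from 5.663 ± 0.685 FPKM to 0.07 ± 0.0608 in the libraries labelled dxo1-1 and 0.1933 ± 0.153 in dxo1-2, while LUX, of the evening complex of the clock, rose from 32.2 to 62.48 and 68.33. Of 13 clock and flowering genes 7 were higher, 3 lower and 3 did not pass (median log2 0.26, positive while camera put the list lower, camera adjusted p = 0.952, fry higher, 0.00387, 4 and 6 when centred). CESA4, a cellulose synthase gene of secondary walls, fell from 3.653 to 1.3 and 1.947; 6 of 7 vascular markers were lower and 1 higher (median log2 -0.46, -0.80 when centred, 0.0222, adjusted p = 0.18 with an estimated correlation). KNOLLE, needed for the cell plate, fell from 26.78 to 10.86 and 14.99, and TSO2, a ribonucleotide reductase gene, rose from 39.31 to 74.51 and 104.2; of 12 cell division genes 3 were higher, 4 lower and 5 did not pass (0.216, 1 and 7 when centred). Of 8 guard cell markers 2 were higher and 4 lower (median log2 -0.35, 0.208, 1 and 5 when centred), with MYB60 up from 7.61 to 16.56 and 18.13. All 3 tested meristem and flower markers were higher (0.522, fry higher, 0.000875, 1 higher when centred), with STM up from 0.69 to 3.543 and 3.303. Of 3 root markers 2 were higher and 1 lower (median log2 0.49, mean -0.06, camera lower, 0.985, fry higher, 0.0143), with TIP2;3 down from 4.463 to 1.997 and 0.3167. Fewer than 3 seed storage markers were measured, so this list was not tested.

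**Figure D2:**
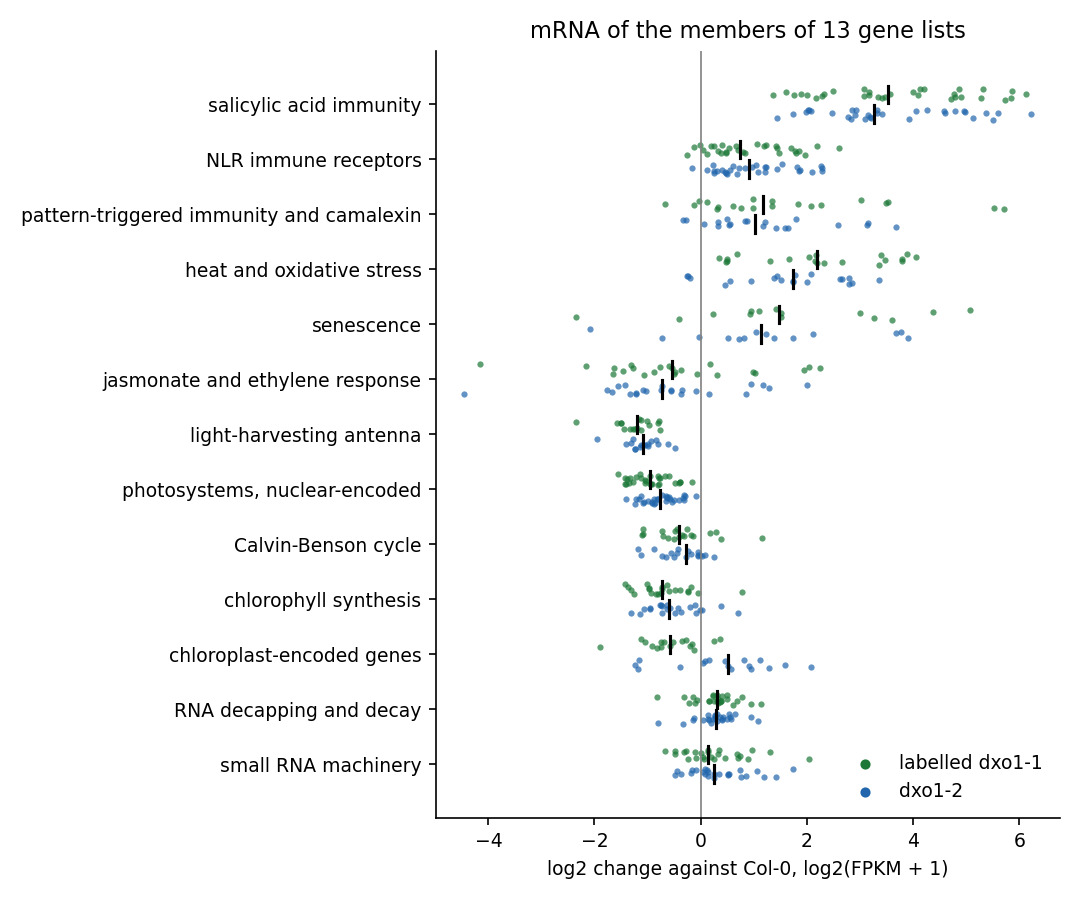
Log2 changes of members of the gene lists of immunity, jasmonate and ethylene, stress, senescence, photosynthesis, chlorophyll synthesis, chloroplast-encoded genes, RNA decay and small RNA machinery. Changes are in the libraries labelled dxo1-1 and in dxo1-2 against Col-0 (n = 3 per group, FPKM). DXO1 itself is higher in the libraries labelled dxo1-1.

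The mutants shared most calls in spite of their opposite DXO1 levels. PR1, PR5, NIMIN1, LHCB6 and AOS moved the same way in both. In both, 8332 genes were higher (4722 if the lists were independent) and 3474 lower (1013 if independent), while 167 went in opposite directions (4409 if independent). Both comparisons share the 3 Col-0 libraries, and simulated groups without a change gave 0 shared calls. The log2 changes correlated at 0.9205 over genes, against 0.51 in the simulation (highest of 50: 0.573), with a covariance of 0.7262 against 0.00902. The controls could not be split into separate sets of at least 2, so part of the excess may come from the shared controls. Between libraries the correlation was 0.975 to 0.978 for the libraries labelled dxo1-1 with dxo1-2, 0.879 to 0.883 for the libraries labelled dxo1-1 with Col-0, 0.906 to 0.908 for dxo1-2 with Col-0, and 0.99 to 0.993 within groups.

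Stress and senescence genes stood lower in dxo1-2 than in the libraries labelled dxo1-1. WRKY45, a senescence regulator gene, differed by log2 -1.86 (adjusted p = 3.9e-08), AOX1D by -1.42 (7.97e-08) and SAG13 by -1.30 (3.9e-08). Of 20 heat and oxidative stress genes 12 were lower, 1 higher and 7 did not pass (13 lower adjusted over the list alone, median log2 -0.61, camera adjusted p = 1.3e-07, adjusted p = 0.231 with an estimated correlation). Of 14 senescence genes 11 were lower and 1 higher (12 and 2 adjusted over the list alone, 7.53e-06, adjusted p = 0.331 with an estimated correlation). Of 20 genes of pattern-triggered immunity and camalexin 9 were lower and 5 higher (0.0168, adjusted p = 0.736 with an estimated correlation), with PAD3 at -2.60 (7.47e-11). Photosystem genes stood higher, 25 of 30 with 1 lower (median log2 0.18, 5.83e-07, adjusted p = 0.736 with an estimated correlation, 17 and 1 when centred), as did 11 of 17 antenna genes (0.00139, adjusted p = 0.741 with an estimated correlation), 14 of 22 chlorophyll synthesis genes with 1 lower (0.000653, adjusted p = 0.736 with an estimated correlation), 10 of 12 cell division genes (0.00171, adjusted p = 0.518 with an estimated correlation) and 10 of 17 chloroplast-encoded genes (12 adjusted over the list alone, 0.0262, adjusted p = 0.741 with an estimated correlation). Of 32 salicylic acid genes 9 were higher and 13 lower, and the list did not pass (0.158). In all, 4101 genes were higher and 2892 lower in dxo1-2 (58.6% higher), against 3523 and 3566 when centred, and 61 and 297 with a fold of at least 2.

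The 22-nt class held more of the small RNA reads in dxo1-2dcl4-2 than in any other line. It made up 57.23 ± 0.491% of the reads of the 3 classes, against 30.84 ± 1.32% in dcl4-2, 22.12 ± 0.676% in dxo1-2 and 22.77 ± 1.32% in Col-0. The nitrate reductase genes NIA1 and NIA2 alone held 48.0 ± 0.0977% of its 22-nt reads, against 0.395 ± 0.0958% in dcl4-2, 0.254 ± 0.0526% in dxo1-2 and 0.07 ± 0.0363% in Col-0. Without the 10 most abundant loci of each class the difference of 26.4 points from dcl4-2 shrank to 6.376, and that of 35.11 points from dxo1-2 to 17.18. The 21-nt share was 45.75 ± 7.49% in Col-0, 43.46 ± 3.73% in dcl4-2, 39.73 ± 3.9% in dxo1-2 and 26.85 ± 1.58% in dxo1-2dcl4-2, and the 24-nt share 31.48 ± 8.8%, 25.7 ± 4.39%, 38.15 ± 4.42% and 15.91 ± 2.07%. The ratio of 22-nt to 21-nt reads was 0.5032 ± 0.0495, 0.7123 ± 0.0547, 0.5595 ± 0.0413 and 2.136 ± 0.111 in the same order. Without the 10 most abundant loci of each class the 21-nt share of dxo1-2dcl4-2 was 32.86% against 33.34% in dcl4-2, a difference of -0.4752 in place of -16.6 points, and the difference in the ratio shrank from 1.423 to 0.2095. The 24-nt difference from dcl4-2 was then -5.901 in place of -9.792 points, and the ratio differed from dxo1-2 by 0.5009 in place of 1.576. Without microRNA genes the 21-nt and 24-nt differences of dxo1-2dcl4-2 were -3.317 and -19.63 points from dcl4-2, and -4.752 and -30.94 from dxo1-2, in place of -12.87 and -22.23. Those of dxo1-2 from Col-0 were -1.93 and 3.423 points, in place of -6.02 and 6.669. Every comparison of dxo1-2dcl4-2 gave an exact p of 0.1 (adjusted 0.16), the lowest that 3 libraries against 3 allow. So did the 22-nt share of dcl4-2 against Col-0, while dxo1-2 against Col-0 gave 0.3 to 0.6.

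**Figure D3:**
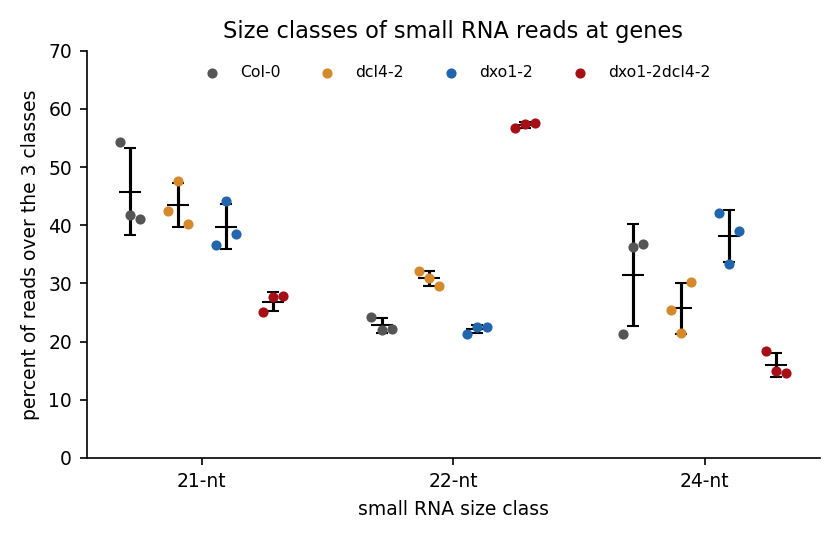
Shares of 21-nt, 22-nt and 24-nt reads in each of the 12 small RNA libraries (% of the reads of the 3 classes, n = 3 per group).

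In dxo1-2 against Col-0, small RNAs appeared at a few protein-coding genes and fell at several microRNA genes and at AT5G38850. UGT84A2, a glycosyltransferase gene, had 0 reads at 21-nt in Col-0 and 536.5 ± 48.5 normalized reads in dxo1-2 (at least 581-fold, adjusted p = 7.1e-10), and at 22-nt rose from 1.462 ± 2.53 to 84.22 ± 4.87 (59.3-fold, 23.0 to 218). At 21-nt EXO, a gene of brassinosteroid-promoted growth, rose from 1.301 ± 2.25 to 57.22 ± 4.11 (46.2-fold, 17.8 to 171), NIA1 from 25.36 ± 6.07 to 308.5 ± 54.7 (11.3-fold) and NIA2 from 26.31 ± 0.274 to 207.6 ± 10.5 (7.9-fold). MIR845b rose at 22-nt from 3.06 ± 4.07 to 309.2 ± 70.3 (87.4-fold, 45.9 to 191). Among microRNA genes MIR167d fell at 22-nt from 442.2 ± 14.8 to 47.79 ± 8.77 (log2 -3.21, adjusted p = 2.77e-07). MIR156f fell at 21-nt from 102.5 ± 15.7 to 15.58 ± 5.69 (log2 -2.73, 0.0029) and MIR827 from 611.5 ± 134 to 153.9 ± 125 (log2 -2.26, 0.00149). Members of a microRNA family can share reads, so the reads at MIR156f are of uncertain assignment. AT5G38850 fell at 22-nt from 522 ± 80.9 to 32.88 ± 19.6 (log2 -4.13, 2.61e-11).

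Chloroplast genes had fewer small RNAs in dxo1-2 than in Col-0 by limma, and edgeR called none of them at 22-nt and 24-nt. PSBA, of photosystem II, fell at 22-nt from 3709 to 2157 (log2 -0.78, adjusted p = 2.63e-12 by limma and 0.354 by edgeR), and RBCL, the Rubisco large subunit gene, from 1951 ± 156 to 884.9 ± 19.5 (log2 -1.14, 0.0915 by edgeR). Of 22 chloroplast-encoded genes 2, 5 and 5 were lower at 21-nt, 22-nt and 24-nt and 0 higher (3, 8 and 9 adjusted over the list alone, camera adjusted p = 5.59e-11, 5.22e-22 and 1.22e-26, adjusted p = 0.0252, 0.000359 and 0.000747 with an estimated correlation). The microRNA list had 2 higher and 11 lower of 124 at 21-nt (median log2 -0.37, 4.69e-15, adjusted p = 0.0765 with an estimated correlation), 1 and 7 of 92 at 22-nt (median log2 -0.77, 7.03e-15, adjusted p = 0.0132 with an estimated correlation) and 0 of 55 at 24-nt (0.000267, adjusted p = 0.0737 with an estimated correlation). Antenna genes passed lower as a list with 0 single calls at 22-nt (0.000115) and 24-nt (2.88e-10), and photosystem genes with 0 at 21-nt (0.00952, adjusted p = 0.0532 with an estimated correlation), 22-nt (1.98e-08) and 24-nt (6.33e-07). Calvin-Benson genes did so with 0 calls at 21-nt (0.0125, adjusted p = 0.0648 with an estimated correlation) and 22-nt (0.00339), and chlorophyll synthesis genes with 0 at 22-nt (0.00136). The nitrate reductase and SMXL list passed higher, with 2 of 4 members at 21-nt (2.97e-06), 1 at 22-nt (9.66e-07) and 1 at 24-nt (0.000831, adjusted p = 0.0752 with an estimated correlation). Pseudogenes passed higher as a list at 22-nt with 1 call among 2943 (median log2 0.50, 8.82e-05) and at 24-nt with 1 among 3623 (0.000628).

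In dxo1-2 against Col-0, 59 features were higher and 15 lower at 21-nt (79.7% higher), 9 and 15 at 22-nt (37.5%), and 2 and 9 at 24-nt by limma. Without any single library of the 6 compared the 21-nt count fell from 74 to between 10 and 21. Centred libraries gave 10 and 15, 4 and 2, and 0 and 0. By edgeR the counts were 38 and 21, 10 and 7, and 0 and 0, where 204 features had an unadjusted p under 0.05 at 24-nt and limma called 11. None of the 24-nt calls of limma passed in edgeR; NIA1, from 8.05 ± 3.3 to 23.0 ± 6.43 (log2 1.49, adjusted p = 0.00435), had 0.191 by edgeR.

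In dcl4-2 against Col-0, 21-nt RNAs of PPR genes fell and 22-nt RNAs appeared at SMXL genes. The near-identical copies AT1G63400, AT1G62914 and AT1G63080, whose reads are of uncertain assignment, went from 2098 ± 330, 2090 ± 326 and 2175 ± 315 normalized 21-nt reads to 2.186 ± 2.9 (995-fold lower, 426 to 3070), 0.456 ± 0.79 (4950-fold lower, 889 to 196000, from 1 read) and 0 (at least 1710-fold lower, adjusted p = 1.5e-12). Of 12 PPR loci 11 were lower at 21-nt (median log2 -6.88, camera adjusted p = 1.91e-60, adjusted p = 2.31e-06 with an estimated correlation), 5 at 22-nt (9 adjusted over the list alone, median log2 -2.61, 6.31e-17) and 3 of 10 at 24-nt (4 adjusted over the list alone, 0.000136), with 0 higher. SMXL4, a gene of the strigolactone repressor family, went at 22-nt from 0 to 268.6 ± 71.0 (at least 246-fold, adjusted p = 3.25e-14), SMXL5 from 0 to 52.48 ± 12.3 (at least 47-fold, 1.64e-09) and NIA1 from 24.69 ± 22.0 to 381 ± 94.2 (log2 4.42, 1.35e-12, 17.9-fold). The nitrate reductase and SMXL list had 3 of 4 higher at 21-nt (median log2 2.86, 2.14e-12) and 22-nt (5.56, 2.01e-18) and 2 at 24-nt (3.07, 1.21e-08).

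Loci of the RefSeq pseudogene biotype, which may include transposable element genes, made up most 22-nt rises of dcl4-2. AT3G43862 rose at 22-nt from 13.14 ± 3.45 to 3223 ± 414 normalized reads (log2 7.91, adjusted p = 3.47e-19) and stood at 24.68 in dxo1-2 and 79.41 in dxo1-2dcl4-2, and AT5G32197 rose from 2.777 ± 0.953 to 695.8 ± 144 (log2 7.75, 2.3e-14); such families have near-identical copies, so their reads are of uncertain assignment. Of 2943 pseudogenes 78 were higher and 1 lower at 22-nt (95 and 3 adjusted over the list alone), 37 and 3 of 2192 at 21-nt and 15 and 3 of 3623 at 24-nt, while the list as a whole did not pass (camera adjusted p = 0.935, 0.881 and 0.158). Single microRNA genes passed: 1 higher at 21-nt, and 1 higher and 1 lower at 22-nt. Chloroplast-encoded genes passed higher at 24-nt with 1 call (3 adjusted over the list alone, 1.91e-07), and antenna genes with 0 calls (0.0298, adjusted p = 0.0883 with an estimated correlation). In all, 43 features were higher and 25 lower at 21-nt (63.2% higher), 87 and 10 at 22-nt (89.7%) and 22 and 9 at 24-nt (71%). The counts were 54 and 28, 111 and 8, and 20 and 5 by edgeR, and 336 and 16, 127 and 3, and 20 and 9 when centred.

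**Figure D4:**
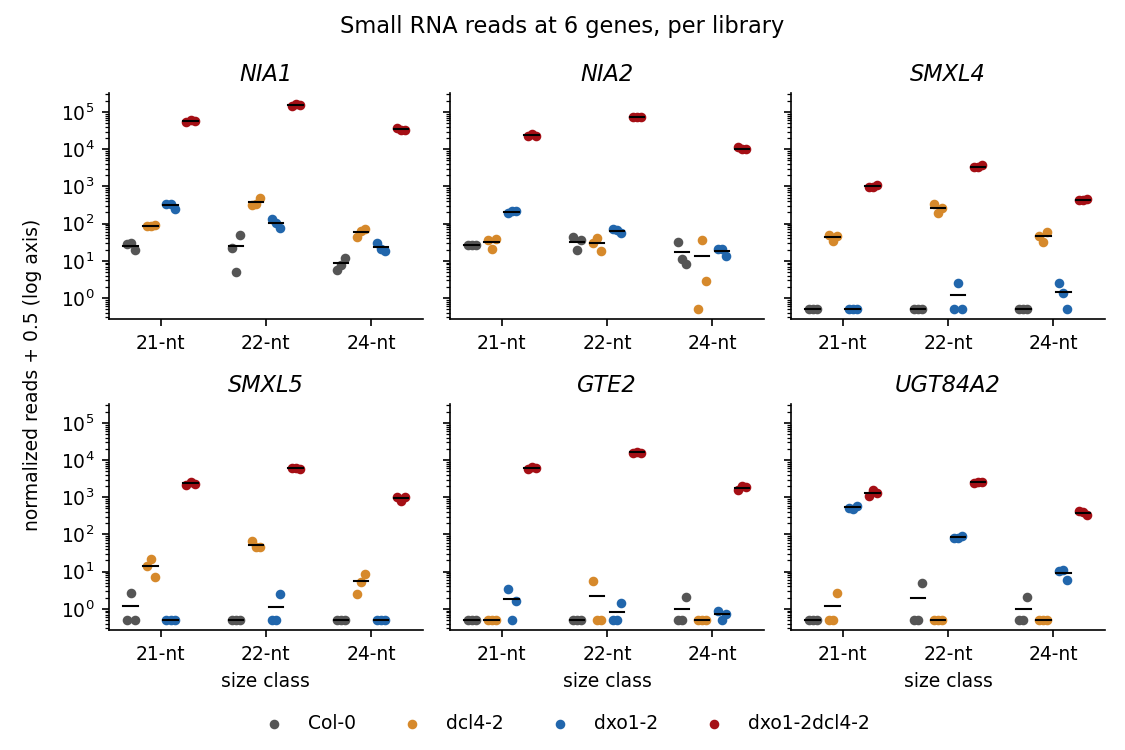
Normalized reads of named loci in each of the 12 small RNA libraries (n = 3 per group, log axis, reads + 0.5).

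In dxo1-2dcl4-2 against dcl4-2, small RNAs of all 3 sizes rose at NIA1, NIA2, GTE2, GTE7 and EXO. NIA1 went at 22-nt from 381 ± 94.2 to 158100 ± 8930 normalized reads (log2 8.72, SE 0.35, adjusted p = 6.82e-22, 397-fold, 370 to 426) and NIA2 from 29.25 ± 10.7 to 74100 ± 1720 (log2 11.35, SE 0.25, 2.92e-31); reads can be shared between these copies. At 21-nt NIA1 reached 57170 ± 3600 and NIA2 23730 ± 1440, and at 24-nt 34620 ± 2390 and 10440 ± 639. GTE7, a bromodomain protein gene, rose at 22-nt from 11.11 to 27020 ± 1590, and its relative GTE2 from 1.754 to 16100 ± 643 (11000-fold, 3760 to 53200, from 3 reads). EXO went from 0 to 5888 ± 361 at 22-nt (at least 4000-fold), CRF4, a cytokinin response factor gene, from 1.169 to 10130 ± 1120, and SMXL5 from 52.48 ± 12.3 to 5966 ± 65.4 (117-fold). All 4 members of the nitrate reductase and SMXL list were higher in every class (median log2 8.41, 7.78 and 8.39 at 21-nt, 22-nt and 24-nt, camera adjusted p = 5.38e-21, 7.01e-24 and 2.93e-18, adjusted p = 0.000304, 0.000124 and 0.00117 with an estimated correlation).

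Photosynthesis genes had fewer small RNAs in dxo1-2dcl4-2 than in dcl4-2. LHCB5 fell at 22-nt from 62.41 ± 10.7 to 3.771 ± 4.27 (log2 -4.65, adjusted p = 7.98e-06), RCA, the Rubisco activase gene, from 184.1 ± 6.55 to 37.81 ± 15.5 (log2 -2.34, 5.78e-07), PETE2, a plastocyanin gene, from 76.86 to 11.02 (log2 -2.78) and RBCL from 1759 to 665.9 (log2 -1.40, adjusted p = 0.00137 by edgeR). At 21-nt, 22-nt and 24-nt, 4, 6 and 9 of 17 antenna genes were lower (6, 10 and 12 adjusted over the list alone, camera adjusted p = 1.46e-06, 4.05e-10 and 5.05e-11), 7 of 30, 6 of 30 and 10 of 29 photosystem genes (18, 13 and 21 adjusted over the list alone, 1.02e-12, 1.3e-09 and 1.12e-11), 4 of 18, 8 of 19 and 5 of 19 Calvin-Benson genes (5.32e-07, 2.15e-08 and 0.000231) and 4, 11 and 5 of 22 chloroplast-encoded genes (1.4e-07, 5.39e-14 and 7.18e-07), with 0 higher. All of these lists passed with an estimated correlation. Chlorophyll synthesis genes had 1 lower at 21-nt (0.0136, adjusted p = 0.0818 with an estimated correlation) and 1 at 22-nt (0.024, adjusted p = 0.107 with an estimated correlation).

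MicroRNA genes moved both ways in dxo1-2dcl4-2 against dcl4-2. MIR169e went to 0 reads from 60.29 at 21-nt and 62.22 at 22-nt (at least 66.4-fold and 76.6-fold lower), and MIR169d and MIR169g, near-identical copies, from 86.25 ± 1.77 at 22-nt to 0 (at least 112-fold lower). Reads can be shared within the MIR169 family, so their assignment to a single member is uncertain. Of 124 microRNA genes 7 were higher and 22 lower at 21-nt (13 and 28 adjusted over the list alone, camera adjusted p = 2.65e-05, adjusted p = 0.283 with an estimated correlation), 7 and 18 of 92 at 22-nt (2.33e-07, adjusted p = 0.0719 with an estimated correlation) and 1 and 4 of 55 at 24-nt (0.00885, adjusted p = 0.198 with an estimated correlation). PPR loci had 4 higher of 12 at 21-nt (7 adjusted over the list alone, median log2 2.19, 2.65e-05, adjusted p = 0.0066 with an estimated correlation), but 1 higher and 2 lower with library size alone; AT1G63080 went from 0 to 7.657 ± 8.75 (at least 6.92-fold, 0.000283). AGO2 rose at 22-nt from 2.305 to 55.93 ± 23.1 (log2 4.87), CYP79B2, of indole glucosinolate and camalexin synthesis, from 2.923 ± 5.06 to 392.3 ± 105 (log2 8.18, 2.01e-06) and the root gene PLT1 from 0 to 28.2 ± 7.0 (at least 19.8-fold); root markers had 2 of 5 higher at 22-nt (0.0177, adjusted p = 0.0719 with an estimated correlation). NLR genes had 1 lower of 16 at 21-nt (0.037, adjusted p = 0.0847 with an estimated correlation), and RPP5 fell at 24-nt from 45.66 to 6.489. Pseudogenes had 17 higher and 40 lower at 21-nt, 34 and 87 at 22-nt (0.655) and 53 and 109 at 24-nt.

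In dxo1-2dcl4-2 against dcl4-2, 183 features were higher and 122 lower at 21-nt (60% higher), 261 and 211 at 22-nt (55.3%) and 143 and 244 at 24-nt (37%). The split depended on the tool and scaling: edgeR gave 108 and 180 (37.5% higher), 164 and 203 (44.7%), and 105 and 248 (29.7%), centred libraries 129 and 162, 157 and 68, and 141 and 127, and library size alone 84 and 480, 118 and 505, and 54 and 1179. Of the limma calls edgeR shared 103 higher and 107 lower at 21-nt, 147 and 164 at 22-nt, and 89 and 197 at 24-nt, with 0 in the opposite direction in any class or comparison.

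In dxo1-2dcl4-2 against dxo1-2, SMXL genes gained small RNAs and PPR genes lost 21-nt RNAs. SMXL5 went at 21-nt from 0 to 2369 ± 224 normalized reads (at least 3870-fold) and SMXL4 from 0 to 1006 ± 71.5 (at least 1630-fold). At 22-nt GTE7 rose from 5.727 to 27020 ± 1590 (log2 12.15), NIA1 by log2 10.59 and NIA2 by 10.15. The PPR copies AT1G63400, AT1G63080 and AT1G62914 fell at 21-nt by log2 -8.26, -8.62 and -8.84, and AGO1, the main Argonaute gene of microRNAs, from 89.17 ± 5.48 to 4.025 ± 6.97 (log2 -5.93, adjusted p = 0.00112). Of 12 PPR loci 11 were lower at 21-nt (median log2 -4.93, camera adjusted p = 6.51e-26, adjusted p = 6.82e-05 with an estimated correlation), 4 at 22-nt (6.21e-10) and 3 of 10 at 24-nt (1.81e-05). All 4 members of the nitrate reductase and SMXL list were higher in every class (22-nt: median log2 11.27, 2.97e-47).

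Photosynthesis genes passed lower as lists in dxo1-2dcl4-2 against dxo1-2, but their medians changed sign with the scaling. Antenna genes had 2 lower at 21-nt (0.0014, median 1.03 when centred) and 4 at 22-nt (4.39e-05, 0.08 when centred), photosystem genes 4 at 21-nt (5.45e-05, 0.35 when centred) and 1 at 22-nt (0.00052, 0.15 when centred), and Calvin-Benson genes 2 at 21-nt (0.000598, 0.37 when centred), 5 at 22-nt (1.67e-06) and 1 at 24-nt. RBCL fell at 21-nt from 1217 to 782.3 by limma (log2 -0.64), with an adjusted p of 0.434 by edgeR and log2 1.303 when centred. PSBA rose at 24-nt from 1010.0 to 3033 (log2 1.58) and PSAA from 79.65 to 198.1, but these were -0.593 and -0.883 with library size alone; chloroplast-encoded genes had 3 of 22 higher at 24-nt (median log2 0.39, 4.06e-06, -1.68 with library size alone). MicroRNA genes had 3 higher and 11 lower of 92 at 22-nt (median log2 -0.30, 0.041, adjusted p = 0.392 with an estimated correlation, 0.97 when centred). Pseudogenes had 1 higher and 15 lower at 22-nt (median log2 -0.56, 0.000446, 0.71 when centred) and 7 and 72 at 24-nt (0.00117). Heat and oxidative stress genes had 1 of 12 higher at 22-nt (0.00284) and root markers 1 of 5 (0.00207). The auxin receptor list had 0 calls in every class and comparison (2 lower at 21-nt and 1 at 22-nt in this one adjusted over the list alone). In all, 113 features were higher and 249 lower at 21-nt (31.2% higher), 155 and 70 at 22-nt (68.9%) and 94 and 117 at 24-nt (44.5%); edgeR gave 118 and 151, 163 and 54, and 88 and 326, centred libraries 788 and 40, 237 and 6, and 82 and 83, and library size alone 60 and 553, 111 and 625, and 53 and 2492.

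The dxo1-2 effect differed between the dcl4-2 and the wild-type background at NIA1, NIA2 and TIC. NIA2 differed by log2 10.30 at 22-nt (adjusted p = 5.42e-24 by limma and 4.19e-09 by edgeR), NIA1 by 7.70 at 24-nt, and TIC, a clock regulator gene, by 11.38 at 21-nt (6.4e-11 by edgeR), with 5897 ± 190 normalized reads in dxo1-2dcl4-2 against 3.955 in dcl4-2, 7.839 in dxo1-2 and 9.32 in Col-0. AT1G15290 at 22-nt stood at 1667 ± 154 in dxo1-2dcl4-2 and at 0 to 4.849 elsewhere. GTE2 at 21-nt (12.06) and 22-nt (13.28) and SMXL5 at 22-nt (6.07) passed in limma only, with an adjusted p of 1, 1 and 0.983 in edgeR; a fitted value of a locus with almost no reads in some groups depends on the pseudocount and is no bound. The pseudogene AT5G32511 stood at 1289 ± 189 in dcl4-2 at 22-nt and at 33.27 in dxo1-2dcl4-2 (-7.05). In all, 64 features had a higher and 59 a lower effect in the dcl4-2 background at 21-nt (52% higher), 100 and 80 at 22-nt (55.6%) and 40 and 27 at 24-nt (59.7%); edgeR gave 50 and 77 (39.4%), 67 and 95 (41.4%) and 21 and 39 (35%), centred libraries 53 and 36, 79 and 30, and 38 and 14, and library size alone 32 and 256, 47 and 332, and 21 and 902.

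The nitrate reductase and SMXL list had a higher dxo1-2 effect in the dcl4-2 background in 4 of 4 members at 21-nt (median log2 6.18, camera adjusted p = 1.84e-21), 3 at 22-nt (6.12, 3.97e-23) and 3 at 24-nt (7.64, 2.97e-19). Photosystem genes had 1 lower of 30 at 21-nt (4.92e-05), antenna genes 0 at 21-nt (0.00668) and 1 of 17 at 22-nt (0.00201), with LHCB5 at -4.32, and Calvin-Benson genes 0 at 22-nt (0.00227). PPR loci had 1 higher of 12 at 21-nt (2 adjusted over the list alone, 0.000343), with AT1G63080 at 3.46 (adjusted p = 0.0247), and pseudogenes 1 higher and 64 lower at 22-nt (0.00972). These lists passed with an estimated correlation.

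Features called in dxo1-2 against Col-0 were often called in the same direction in dxo1-2dcl4-2 against dcl4-2. EXO rose in both at 21-nt. At 21-nt 20 features were higher in both (1.37 if independent) and 8 lower (0.232), at 22-nt 6 (0.276) and 11 (0.372), and at 24-nt 1 (0.0338) and 5 (0.259), with 2, 2 and 0 opposite. These comparisons share no library, but they share one estimate of the spread of each feature. Features with many reads are also called more easily in both, so the numbers for independent lists are likely too low. Against the mRNA changes of dxo1-2, measured at another age, genes with fewer small RNAs in dxo1-2dcl4-2 than in dcl4-2 were lower in mRNA in 30 cases at 21-nt (13.8 if independent), 41 at 22-nt (21) and 42 at 24-nt (18.7). They were higher in mRNA in 9 cases (27.6), 16 (42.3) and 18 (36.9). Genes with more small RNAs were higher in mRNA in 81 (74.4), 109 (101) and 42 (40.1) cases, and lower in 33 (37.3), 38 (50.2) and 16 (20.3). The Spearman correlation over genes was 0.188, 0.196 and 0.152, and 0.103, 0.105 and 0.096 for dxo1-2 against Col-0.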

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

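The tests for degradation fragments and for exchanged labels, the fit with Col-0 replicate 2 as the only control and the medians by gene length were chosen after the result was seen, and all patterns weighed were found in the same data.

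The dxo1-2 effect on small RNAs differed between the dcl4-2 and the wild-type background at 123 features at 21-nt, 180 at 22-nt and 67 at 24-nt, which is a difference between groups by the test of that contrast. Ranked by fitted value, which depends on the pseudocount where a group had few or 0 reads, the largest differences at 21-nt were at GTE2 (log2 12.06), TIC (11.38) and AT1G15290 (9.87) on the higher side and at AT2G10310 (-7.14), AT2G36470 (-7.26) and SAG20 (-7.96) on the lower side. At 22-nt they were at AT1G15290 (14.36), GTE2 (13.28) and APR3 (13.01), and at AT5G32511 (-7.05), AT4G06517 (-7.15) and AT4G36850 (-7.78). At 24-nt they were at CRF4 (12.21), GTE2 (12.03) and NIA2 (11.12), and at AT4G03530 (-5.83), AT5G51400 (-6.78) and AT2G13240 (-7.03). GTE2 at 21-nt and 22-nt had an adjusted p of 1 by edgeR. Between dxo1-2 and the libraries labelled dxo1-1, 6993 mRNAs differed.

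Other groupings of the same libraries gave fewer calls in most comparisons. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In mRNA 1 of 10 reached the real count in each comparison: 13902 calls against 2 in the highest other split for the libraries labelled dxo1-1, 13410 against 3 for dxo1-2, and 6993 against 2 between the mutants. For the mean of both alleles 1 of 100 did, with 14196 calls against 10490. In small RNA 1 of 10 did in every comparison of a pair of lines. At 21-nt these were 74 against 1 (dxo1-2 and Col-0), 68 against 2 (dcl4-2 and Col-0), 305 against 0 (dxo1-2dcl4-2 and dcl4-2) and 362 against 10 (dxo1-2dcl4-2 and dxo1-2). In the same order they were 24 against 1, 97 against 1, 472 against 0 and 225 against 0 at 22-nt, and 11 against 1, 31 against 1, 387 against 3 and 211 against 1 at 24-nt. For the difference between backgrounds 3 of 100 reached 123 at 21-nt (highest 203) and 3 of 100 reached 180 at 22-nt (highest 291). At 24-nt 5 of 100 reached 67 (highest 196). A regrouping can keep the effect within the dcl4-2 background in full, so these shares do not decide on chance in any class. The highest grouping in each class exchanged all labels within a background, which turns the difference into a sum of both effects. The other groupings that reached the real count mixed the lines of the wild-type background and kept those of the dcl4-2 background apart. They gave 133 calls at 21-nt, 186 at 22-nt, and 83, 100 and 72 at 24-nt. The effect within the dcl4-2 background thus stayed in their contrast.

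Small RNAs rose at NIA1, NIA2, GTE2 and GTE7 in dxo1-2dcl4-2 over dcl4-2. If they were degradation fragments of abundant mRNAs, the 200 genes with the highest FPKM in dxo1-2 should have gained too. Their median log2 change at 22-nt was -0.7151, with 5 higher and 23 lower. The FPKM came from dxo1-2 at 16 days, and no mRNA was measured in the dcl4-2 background. Abundant mRNAs include photosynthesis genes that fell in dxo1-2, where fragments that follow mRNA would fall too. This test therefore does not decide about fragments at NIA1, NIA2, GTE2 or GTE7. If the rises came from size factors distorted by a few loci, few should remain with library size alone. Of 261 rises edgeR tested 158, and 118 of these remained (74.68%), which argues against this explanation for the rises tested. Secondary siRNA production at NIA1, NIA2, GTE2 and GTE7 when both DXO1 and DCL4 are impaired may be the cause. The values do not show this.

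DXO1 stood at 212.2 FPKM in the libraries labelled dxo1-1 and at 10.93 in Col-0. If labels were exchanged with Col-0 and the mutants resemble each other, Col-0 would lie nearer to dxo1-2 than these libraries do, but their lowest correlation with dxo1-2 was 0.975 and the highest of Col-0 with dxo1-2 0.908. A raised copy number or transcription of the region would raise its neighbours, but the 4 nearest tested genes had a median log2 change of 0.4269 (CBL1 0.35, AT4G17616 -0.87, CKB2 0.74, AT4G17650 0.50). Both tests argue against these explanations, and libraries from another line were not tested for. A transcript driven from within an insertion could be the cause, which a gene-level FPKM does not show.

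More genes were higher than lower in the mRNA of both mutants, and the 50 most abundant genes held 32.0% of the FPKM total in Col-0 and 20.33% and 20.3% in the mutants. Without 71 abundant genes and rescaled, the median change was -0.03271, with 6933 higher and 7302 lower (48.7% higher against 67.9%), so a different share taken by abundant transcripts stays open as a candidate explanation. With Col-0 replicate 2 as the only control, whose fragment length is that of the mutants, the median was 0.1826, with 8067 higher and 4179 lower. A single control library excludes nothing, and the median was 0.39 in genes under 1000 bases and 0.06 in genes of 3000 or more, so fragment length stays open too. No biological explanation of the excess was tested, and the lower photosynthesis genes are themselves among the abundant ones.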

How the results depend on the processing

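Most calls of named mRNAs and mRNA lists held, but which side held more of all mRNAs turned when centred (6385 higher, 8214 lower) and with quantile normalization (6488, 7931), and small RNA counts depended on the scaling and on single libraries. Of 672 mRNA list results 655 kept their call and 17 lost it, and of 1423 in small RNA 1362 and 61. Of 1630 results of named mRNAs 1607 kept it, 21 lost it and 2 reversed, and of 3459 in small RNA 3141, 314 and 4. The fits with genes of at least 1000 bases, with Col-0 replicate 2 as the only control, and by edgeR with TMM factors over the 3 classes summed were chosen after the data were seen. Not run: DESeq2 for mRNA, which has no counts. A fit of only the 2 groups gives no value for the mean of both alleles or the difference between backgrounds. List tests were not computed for count tests and for fits of 2 groups, nor named genes and lists for a fold of at least 2. Where no reason is given, the cause was not tested.

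Reversed: AFB3 -0.00948 with quantile normalization, DCL4 -0.0903 and RBCL at 21-nt (dxo1-2dcl4-2 vs dxo1-2) 1.303 when centred, and without TMM factors at 24-nt PSBA -0.593 and PSAA -0.883 (dxo1-2dcl4-2 vs dxo1-2) and PSBA -1.23 (difference between backgrounds); the scaling constructs these. The 22-nt to 21-nt ratio of dxo1-2 vs Col-0 was -0.00623 without microRNA genes, and the 21-nt share of dxo1-2dcl4-2 vs dxo1-2 0.840 without the 10 most abundant loci.

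A fold of at least 2 left 4089 mRNAs in the libraries labelled dxo1-1, 3449 in dxo1-2, 3698 in their mean and 358 between them, by its construction. For dxo1-2 vs Col-0 the small RNA calls (74, 24 and 11 at 21-nt, 22-nt and 24-nt) became 120, 71 and 42 with DESeq2, 133, 67 and 41 with only the 2 groups, and 25, 6 and 0 when centred. They became 36 at 21-nt with pseudocount 0.1, and 39 at 22-nt and 6 at 24-nt with at least 10 reads in 3 libraries. At 24-nt they became 0 with edgeR, 6 with TMM within the class and 3 without TMM. For dcl4-2 vs Col-0 at 21-nt (68) they became 103 with DESeq2 and 352 when centred. For dxo1-2dcl4-2 vs dcl4-2 they became 225 at 22-nt when centred (472), 201 at 24-nt with only the 2 groups (387), and 564 at 21-nt (305) and 1233 at 24-nt without TMM. For dxo1-2dcl4-2 vs dxo1-2 they became 828 at 21-nt when centred (362), 613, 736 and 2545 without TMM (362, 225 and 211), and at 24-nt 414 with edgeR, 336 with TMM within the class, 438 with DESeq2 and 100 with only the 2 groups. For the difference between backgrounds (123, 180 and 67) they became 60, 116 and 36 with pseudocount 0.1, 288, 379 and 923 without TMM, 203 at 21-nt and 115 at 24-nt with DESeq2, 198 at 21-nt with at least 10 reads, and 109 at 22-nt when centred.

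Leaving out each library in turn gave 13291 to 13860 mRNA calls for the libraries labelled dxo1-1, 12751 to 13406 for dxo1-2, 13459 to 14026 for their mean, 5647 to 7462 between them, 11208 to 11565 shared, 41 to 43 list calls, and 396 to 605 genes called in both assays. At 21-nt it gave 10 to 83 for dxo1-2 vs Col-0, 48 to 75 for dcl4-2 vs Col-0, 219 to 351 for dxo1-2dcl4-2 vs dcl4-2, 188 to 372 vs dxo1-2 and 72 to 131 for the difference between backgrounds. At 22-nt it gave 17 to 31, 82 to 103, 334 to 469, 140 to 252 and 141 to 177, and at 24-nt 5 to 12, 20 to 35, 252 to 520, 104 to 314 and 44 to 83. Small RNA list calls were 78 to 89. A count moved over 1.5 times at 21-nt for dxo1-2 vs Col-0 without any of its 6 libraries (14, 16 and 15 without Col-0 replicates 1, 2 and 3, and 15, 10 and 21 without dxo1-2 replicates 1, 2 and 3). For dxo1-2dcl4-2 vs dxo1-2 it moved without dxo1-2 replicates 1, 2 or 3 at 21-nt (192, 188, 204) and 24-nt (118, 104, 134), and without 1 or 2 at 22-nt (140, 147). It moved for the difference between backgrounds without dxo1-2 replicates 1 or 2 at 21-nt (75, 72) and 2 at 24-nt (44). At 24-nt it also moved for dxo1-2 vs Col-0 without Col-0 replicates 1 or 2 (5 each) or dxo1-2dcl4-2 replicate 2 (7), for dcl4-2 vs Col-0 without Col-0 replicate 2 (20), and for dxo1-2dcl4-2 vs dcl4-2 without dcl4-2 replicate 3 (252). A smaller group has less power.

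Shares at 21-nt, 22-nt and 24-nt and the 22-nt to 21-nt ratio ranged over -8.37 to -1.70, -1.07 to 0.108, 1.59 to 9.35 and 0.0280 to 0.0802 for dxo1-2 vs Col-0, -4.64 to 2.03, 7.44 to 8.82, -10.9 to -3.09 and 0.181 to 0.24 for dcl4-2 vs Col-0, -18.2 to -14.5, 25.7 to 27.0, -11.9 to -7.53 and 1.36 to 1.46 for dxo1-2dcl4-2 vs dcl4-2, and -14.4 to -10.7, 34.7 to 35.4, -24.6 to -20.3 and 1.51 to 1.61 vs dxo1-2. Without Col-0 replicate 1 the 22-nt share of dxo1-2 vs Col-0 (0.108) and the 21-nt share of dcl4-2 vs Col-0 (2.03) changed sign.

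With the replicate number as a replicate block, counts were 13897, 13367, 14160 and 6925 in mRNA and 56, 64, 275, 307 and 102 at 21-nt, and no count moved over 1.5 times. Among named genes and lists the calls of AT5G38850 at 21-nt and of AT5G51400, PETE1 and ZAT10 in the difference between backgrounds were lost. Deviations from group means correlated at -0.03 to 0.09 between mRNA libraries of the same number and at -0.1 to 0.09 between others, so the numbers do not pair samples.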

Other observations

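The tests and tallies of the pseudogenes and the test of clustering around DXO1 were chosen after the result was seen.

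Pseudogenes by RefSeq biotype, which may include transposable element genes, were mostly lower in dxo1-2dcl4-2 where 22-nt levels in dcl4-2 were high. They stood near the level of dxo1-2. AT5G31719 stood at 16.75 normalized 22-nt reads in Col-0, 1523 in dcl4-2, 30.69 in dxo1-2 and 41.3 in dxo1-2dcl4-2, AT5G29975 at 28.93, 1393, 47.29 and 58.7, and AT2G09187 at 21.52, 1257, 36.22 and 58.05. Of 87 features that rose in dcl4-2 at 22-nt 78 were pseudogenes, against 2943 pseudogenes among 8498 tested (Fisher p = 7.859e-27, odds ratio 16.77). Near-identical copies can share reads, so features are not independent and this p overstates the evidence. The 78 were chosen for high values in the same dcl4-2 libraries that dxo1-2dcl4-2 is compared with. Of these 78 the mean of dxo1-2dcl4-2 lay closer to Col-0 than to dcl4-2 on the log2 scale in 68 (87.18%). The test of dxo1-2dcl4-2 against dcl4-2 was passed by 61 as lower. By means, dxo1-2dcl4-2 stood at over 2 times the Col-0 level in 55 and at over 2 times the dxo1-2 level in 7. In dxo1-2 itself 74 stood above Col-0 (33 at over 2 times). An active state of these loci in the single dcl4-2 line that was not passed to the cross may explain this, as may suppression that depends on dxo1-2, and the values do not separate them.

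Genes that gained 22-nt reads in dxo1-2dcl4-2 over dcl4-2, such as NIA1, NIA2 and EXO, were asked whether they were highly expressed in dxo1-2. Of these genes 189 were tested in both assays, and they did not stand out from the 4606 genes so tested. Their median of 40.31 FPKM lay at percentile 51.56 of random lists drawn from the 4606 (all of them 40.18, upper limit of the central range 51.49). Genes with too few 22-nt reads to be tested were left out. The test therefore does not compare the gaining genes with all mRNAs. In dxo1-2 the mRNA change of the gaining genes lay slightly above that of random lists matched on FPKM. The median log2 change of the gaining genes was 0.3476, at percentile 98.87 of 10000 such lists (median 0.2112, central range 0.1032 to 0.328). By calls, 109 were higher in mRNA (101 if independent) and 38 lower (50.2). The lists were not matched on gene length, with which the mRNA shift varied. In the mean of both alleles it was 0.39 in genes under 1000 bases and 0.06 in genes of 3000 or more. The mRNA and small RNA came from plants of different ages, and the mRNA contrast is in the wild-type background.

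CSLA01, AT4G13575 and AT4G13860 were among the 5 mRNAs that fell most in both mutants. They lie at -93, -348 and -328 tested genes from DXO1 on chromosome 4, which prompted a test of clustering. Of the 1000 tested genes nearest to DXO1 in order 6 had a log2 change of -2 or less in both mutants, against 40 of 17243 elsewhere (Fisher p = 0.0385). That count includes the 3 genes that prompted the test. Without the 5 most reduced genes 3 of 997 stood against 38 of 17241 (odds ratio 1.366, 95% interval 0.2694 to 4.318, Fisher p = 0.4897). This window thus gives no independent sign of clustering and leaves it open. Just outside the window lay further losses in both mutants, AT4G11320 (at -501 genes), AT4G11211 (-509), AT4G10910 (-532) and AT4G25780 (594). Other windows were not tested.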
